A study of Rattus norvegicus with 8 samples.

How the data were processed

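Labelled RNA of 8 rat livers was hybridised to 2-colour arrays, 4 from LPS-treated and 4 from Control rats. Per the labels' protocols, total RNA was extracted from liver, amplified through repeated rounds of RT/IVT and labelled. On every array a Control liver pool was in Cy3 (channel 1) and the single animal in Cy5 (channel 2). Dye and treatment were thus never exchanged. The pool and dye cancel in the difference between groups only where the pool channel reads alike on the arrays of both groups. The submitters' processing notes name Agilent Feature Extraction 8.5.1.1. Background correction, normalization and any genome build are not given in the sources used here. The labels call the Control animals untreated in the titles and saline-injected in the growth protocol, and the makeup of the pool is not stated. Animals were labelled as biological replicates.

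The authors deposited a table of log10 ratios, used here as the main values, which were multiplied to the log2 scale. Each column had a median of 0, and each equals log10 of Intensity 2 over Intensity 1 of a column pair in the second table, within the printed digits, for all 8 arrays. The deposited intensity values are relative, with a median probe intensity of 0.148, and they are printed in steps of 0.01, with finer steps only below 0.01. This rounding puts 19.1% to 38.4% of the ratios of an array at exactly 0, and 35.6% of values have both intensities under 0.1, so small changes of dim genes are coarse. The pool channel's intensities served only for the ratio and for a check of the direction. Over 94 probes changed at least 4-fold and brighter than 0.5, the median absolute difference between the groups was log2 0.14 in the pool channel and 2.68 in the animal channel. The authors' deposited table also gives a p-value per probe and array, whose calculation is not stated. In the authors' deposited table, 1.57% to 3.01% of probes on a Control array and 15.0% to 16.0% on an LPS array have p under 0.01.

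The column headers of the intensity table name 1 LPS array a middle dose of 100 mkd and the others a high dose of 1000 mkd, all at day 2, while the labels give 3 mg per kg and 24 hours for all 4. The unit mkd is not explained. The labels were followed, and the array under the other header has the values of LPS replicate 1. No ratio was given for 542 probes on 1 or more arrays, 143 of them with a mean intensity above 30 and 314 under 0.1. Genes measured on fewer arrays are given with their number of values.

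Gene names came from the deposited table and were updated through the RefSeq gene table of assembly GRCr8. Of 23614 probes, 16738 had a gene name, 4176 of them through a RefSeq accession, 3094 names changed and 6876 probes had no name. Updated names were found in that table for 16271 probes. Probes of 1 gene were averaged, also where 1 of them lacked a value on some array. Of 2022 genes with several probes, 38 had probes called in opposite directions. Unnamed probes stayed in the fit as their own rows and are not counted as genes; 607 of them were higher and 948 lower.

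The difference of LPS and Control was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over 21161 rows with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. Errors beside log2 changes are standard errors of that fit, with 4 arrays per group unless stated. For 171 rows no array varied. The Control and the LPS arrays were also each tested against 0, that is against the pool. Of each of 35 gene lists, the shift was tested with camera (preset correlation 0.01) with adjustment over the lists, and with camera at an estimated correlation, with fry, and with an exact permutation test of the list mean over 70 assignments of the arrays. The lists, the tests and the alternatives were chosen before the data were examined, except where stated. Some lists share genes, such as Lcn2 in the acute phase and iron lists and Serpina1 in the acute phase and hepatocyte lists. The hepatocyte list also shares Alb, Ttr, Tf, Ahsg and Apoh with the plasma protein list. It shares Cps1, Tat and Hpd with the amino acid list.

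Named genes follow a rule. They are the 10 largest rises and 10 largest falls among genes past the test with a proper name and no overlap between groups, up to 4 members past the test with the largest change of each list, or 2 members as values where fewer than 2 passed, and A2m, Lbp, Crp, Alb, Tnf, Il6, Il1b, Nos2, Cd14, Tlr4, Cyp2c11, Cyp3a2, Cyp2e1, Cyp7a1, Slc10a1, Abcb11, Abcc2, Abcb1b, Nr1i2, Nr1i3, Rxra, Hamp, Igf1 and Bmal1 (Arntl). Genes named outside it were chosen after their values were seen. Values of some list members are not reported here. The lists of sex-biased liver genes were written after the data were examined.

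The fit was tested on simulated data with the spreads and missing values of the real probes. In the simulated LPS against Control comparison over 14297 genes, 200 genes were changed. Of 50 genes per size, 46% were called in the right direction at a log2 change of 0.5, 80% at 1, 96% at 2 and 98% at 4. Of 175 calls, 5 were unchanged genes, and the shifted list was called with 0 other lists. The simulated noise was drawn independently for each probe and was not rounded. It therefore does not show how list calls fare where genes move together, or how calls of dim, coarsely printed genes fare. Alternatives covered the source table, the normalization, filters on dim or missing probes, the variance model, array weights, the choice of probe, the replicate number as a block, leaving out each array, and other thresholds. Figures were drawn with matplotlib 3.10.9.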

Results

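Liver RNA of 8 Sprague Dawley rats was measured on 2-colour oligonucleotide arrays, 1 array per animal. Of these, 4 rats had received lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria, which Toll-like receptor 4 senses) at 3 mg per kg into the peritoneum, and 4 Control rats had received 0.9% saline. Livers were taken after 24 hours. Each array set the animal's RNA (Cy5) against 1 pool of Control liver RNA (Cy3), so each value is a log2 ratio of animal over Control pool. Each array gave a ratio for 23407 to 23528 probes, and the number of arrays limits the precision. The comparison asks which transcripts were higher or lower in the liver after endotoxin.

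LPS changed 25.6% of the measured liver genes. More members were higher than lower among cytokines and chemokines (13 higher and 2 lower of 29), neutrophil and monocyte markers (11 and 0 of 22), acute phase proteins (11 and 1 of 21) and genes of cholesterol synthesis (20 and 0 of 25). More were lower among genes of phase I drug metabolism (23 lower and 2 higher of 35), fatty acid oxidation (16 and 0 of 25) and amino acid catabolism (11 and 1 of 29) and plasma proteins that inflammation lowers (7 and 1 of 12). Camera called these 8 lists with a preset correlation, and 0 of them with an estimated correlation (adjusted p = 0.133 to 0.254). With limma at an adjusted p under 0.05, 1976 genes were higher and 1689 lower in LPS among 14297 named genes tested. At least 2-fold changes were found for 355 higher and 198 lower genes, and the median absolute log2 change of all called genes was 0.51. The 4 LPS and 4 Control values did not overlap for 29.0% of the genes measured on every array, where chance gives 2.86%. Without Control replicate 3, which stood apart from the other Control arrays, 1804 genes were higher and 1589 lower, and without LPS replicate 1, whose column header names another dose, 1749 and 1443. Setting the reference genes' mean to 0 in every array moved the median change of all genes from -0.03 to -0.14 on the log2 scale and the share of higher genes among the calls from 53.9% to 32.0%. The counts fell to 643 higher and 417 lower after quantile normalization and to 452 and 318 after scale normalization.

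Against the Control pool, limma called 0 of 23555 probes over the 4 Control arrays, with 143 (0.607%) at an unadjusted p under 0.05, where chance gives 5%. The linear Control ratios of 49 genes that varied widely averaged to within a median of log2 0.031 of the pool, and with a Control mean so close to the pool this count sets no background level. Over the 4 LPS arrays, 4256 probes lay above and 5301 below the pool, 9557 in all, and 6279 without LPS replicate 3. The LPS arrays correlated with one another over all probes at r = 0.69 to 0.75, and the Control arrays at r = -0.24 to 0.00, as values of genes within arrays and not as independent replicates. The first principal component held 49.0% of the variance and parted the groups.

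Among the single genes with the largest rises were chemokines that attract T cells and monocytes and the calprotectin subunits of neutrophils. Cxcl9 rose by log2 4.84 ± 0.20 (SE, 4 arrays per group, adjusted p = 5.16e-05), which is 28.7-fold, S100a9 by 4.79 ± 0.23, S100a8 by 4.32 ± 0.40, Ccl2 by 4.15 ± 0.32 and Ccl3 by 3.72 ± 0.32. The size for Cxcl9 depends on a pool channel that was not constant, at 0.43 to 2.28 over the arrays. Its Control animals read 0.32 to 0.64 at a mean linear ratio of 1.02, so the high pool readings were on LPS arrays. The animals' mean intensities were 0.49 in Control and 56.1 in LPS, a larger difference than the ratios give. Pla1a, a phosphatidylserine phospholipase, rose by 3.60 ± 0.14, Il1b, the cytokine interleukin-1 beta, by 3.47 ± 0.22, and Reg3b, a secreted C-type lectin, by 3.36 ± 0.37. The Control animals' intensities were 0.01 to 0.02 for S100a8, 0.02 to 0.04 for Reg3b, 0.04 to 0.07 for Ccl3 and 0.06 to 0.11 for Ccl2, not far above the printed step of 0.01, so the direction of these rises rests on the LPS intensities (means of 0.703, 0.438, 0.835 and 1.70) and their size and rank are coarse. The top of the list was a probe named Hps5, at log2 5.64 ± 1.45 (adjusted p = 0.0265), whose Control arrays spread by an SD of 3.24. Alpha-2-macroglobulin (A2m), the classical acute phase protein of the rat, rose by 3.75 ± 1.00 (adjusted p = 0.0309) with a Control SD of 2.24. Hps5 and A2m both lost the call when any array other than Control replicate 3 was left out, with log2 changes from 4.85 to 5.70 and from 2.94 to 3.83, and without Control replicate 3 they stood at 7.20 and 4.73. Set against the mean of the linear Control ratios, a comparison chosen after the data were seen, the changes were 2.88 for Hps5 and 2.49 for A2m, which ranked Hps5 9 and A2m 10 among these 10 genes, with Cxcl9 first at 4.80. The largest falls were those of Inmt, an N-methyltransferase, at log2 -4.17 ± 0.33 (adjusted p = 0.000289), the zinc finger gene Zfp354a at -3.97 ± 0.33, serine dehydratase (Sds) at -3.29 ± 0.49, the corticosteroid-binding globulin gene Serpina6 at -3.25 ± 0.24 and the steroid dehydrogenase gene Hsd17b2 at -3.20 ± 0.44. Nr0b2 (SHP, a nuclear receptor of bile acid feedback) fell by 3.16, with an SE of 0.63 (-3.75 without LPS replicate 1), and Mmd2 stood at -3.07, Cyp3a85-ps at -3.02, Colq at -2.91 and Crym at -2.85.

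**Figure D1:**
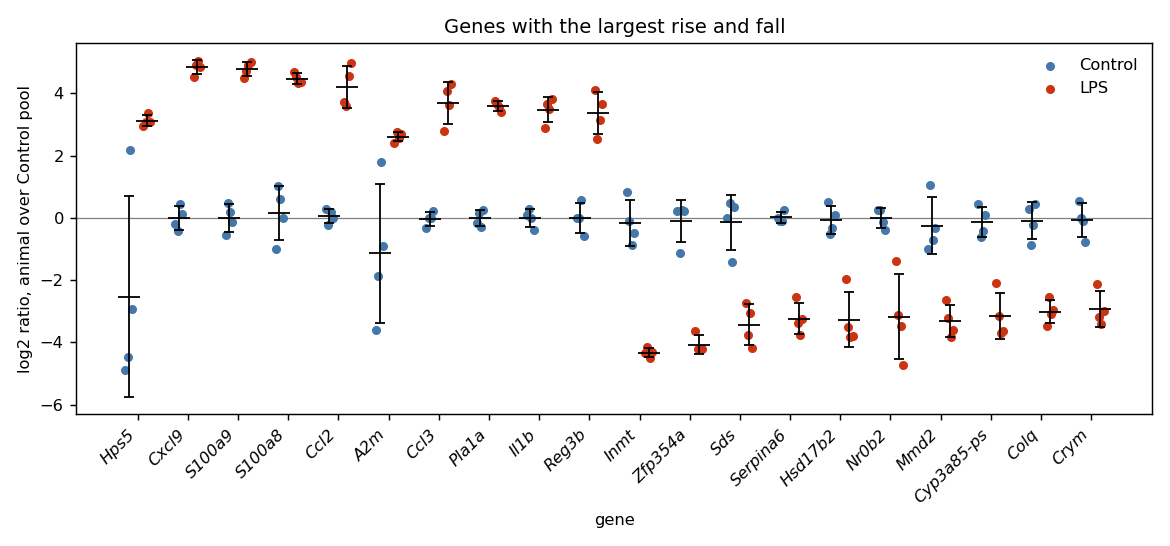
Log2 ratio of animal over Control pool (vertical axis) for the 10 genes with the largest rise and the 10 with the largest fall, as points for the 4 Control and 4 LPS animals with black lines at the mean and bars of 1 SD. The rule that chose these genes required no overlap between the groups. The Control values of Hps5 and A2m spread with SDs of 3.24 and 2.24.

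Markers of other liver cell types moved with LPS. Of 22 measured neutrophil and monocyte markers, 11 were higher and 0 lower (the same counts adjusted over the list alone), with a median log2 change of 0.50. Besides S100a8 and S100a9, the gelatinase Mmp9 rose by 2.70 ± 0.19 and lysozyme (Lyz2) by 1.76 ± 0.26. This list's shift had a camera adjusted p of 1.34e-05, and adjusted p = 0.133 with an estimated correlation. Control replicate 3 stood at 0.06 in the list mean, with the other Control arrays at -0.07 to -0.03 and the LPS arrays at 0.81 to 1.13. Of 21 lymphocyte markers, 8 were higher and 0 lower (12 and 1 adjusted over the list alone), with a median of 0.41. They include the cytotoxic granule genes Nkg7 (1.21 ± 0.18) and Prf1 (0.79 ± 0.17), the leukocyte gene Ptprcap (0.88 ± 0.18) and Cd5 (0.95 ± 0.26). The lymphocyte shift had a camera adjusted p of 0.000365, and adjusted p = 0.284 with an estimated correlation, and 4 members were higher without Control replicate 3 and 5 without Control replicate 1, LPS replicate 3 or LPS replicate 4. Without LPS replicate 3, 1 member was lower. Cd5 lost its call without any 1 of 6 arrays, every one but LPS replicates 1 and 2, with log2 changes from 0.87 to 1.01.

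Stellate cell and fibroblast markers were higher for 7 and lower for 2 of 16 members (8 and 2 adjusted over the list alone), with a median of 0.37. Timp1, an inhibitor of matrix proteases, rose by log2 3.26 ± 0.11, decorin (Dcn) by 1.62 ± 0.36, vimentin (Vim) by 1.59 ± 0.09 and Rgs5 by 1.13 ± 0.10, while the matrix genes Reln and Col3a1 were lower, at -0.90 and -0.85. Camera gave an adjusted p of 0.000639, and adjusted p = 0.133 with an estimated correlation. Erythroid markers were lower for 4 and higher for 0 of 11 members (5 and 0 adjusted over the list alone), with a median of -0.54. The globin genes Hbb (-1.97 ± 0.32), Hba-a1 (-1.55 ± 0.23) and Hba-a2 (-1.55 ± 0.23) and Alas2 (-1.19 ± 0.19), the erythroid enzyme of heme synthesis, fell, with a camera adjusted p of 0.0101 and adjusted p = 0.201 with an estimated correlation.

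Hepatocyte markers were lower for 6 and higher for 1 of 13 members (9 and 1 adjusted over the list alone), with a median of -0.58. Albumin (Alb) fell by 1.35 and Apoa2 by 0.91, and Ahsg, counted among the 6, stood at -1.07 with a value on 1 Control array. Serpina1, at log2 1.95 ± 0.09, rose, on a dim probe whose 4 Control ratios were all 0, so the Control arrays add no measured spread to this SE. For this list the camera adjusted p was 0.0357, and adjusted p = 0.181 with an estimated correlation. The call ended without Control replicate 4 (adjusted p = 0.0575), with quantile (0.122) or scale normalization (0.206), array weights (0.0523), the brightest probe per gene (0.0756) or the reference genes' mean at 0 (0.0848), and over all alternatives at the preset correlation the adjusted p ranged from 0.00570 to 0.206. Kupffer cell and macrophage markers showed no common shift, with 2 higher and 3 lower of 16 (4 and 5 adjusted over the list alone) and a camera adjusted p of 0.816. Among them Clec4f, the Kupffer cell lectin, fell by 2.30 (SE 0.22), Mrc1 by 0.59 and Vsig4 by 0.45, while Adgre1 rose by 1.06 ± 0.16 and Lyz2 rose as given above. Without LPS replicate 1, 6 were lower. Endothelial markers were higher for 7 and lower for 3 of 15 (7 and 4 adjusted over the list alone), with a camera adjusted p of 0.0900 (0.0395 without LPS replicate 3, and 0.0395 to 0.209 over the alternatives at the preset correlation). Esam rose by 0.97 and Emcn by 0.55, while Dnase1l3 fell by 0.63, Kdr by 0.53 and Stab2 by 0.46; Emcn lost its call without any 1 of the 4 LPS arrays, at log2 0.52 to 0.57. Bile duct markers had 2 members higher of 11 (2 adjusted over the list alone, camera adjusted p = 0.0512), namely Cftr at 0.65 and Anxa4 at 0.36. Anxa4 lost its call without Control replicate 1 or LPS replicates 1 or 4, at 0.32 to 0.35, which left 1 member higher, and with the reference genes' mean at 0 (0.26). Without Control replicate 2, 1 member was lower. The bile duct list passed without Control replicate 2 (adjusted p = 0.0415), LPS replicate 2 (0.0298) or LPS replicate 3 (0.0356), and with loess, the brightest probes, no 25% dimmest probes or a variance trend, with a range of 0.0237 to 0.265 over the alternatives at the preset correlation. Pancreas and fat markers had 4 lower of 15 (5 adjusted over the list alone, camera adjusted p = 0.0935), with Cela1 at -1.47, Cfd at -0.91, Plin1 at -0.53 and Prss1 at -0.22. Prss1 lost its call without any 1 of 6 arrays, every one but Control replicates 1 and 4, at -0.22 to -0.18, and with loess (-0.16). This list passed without the 25% dimmest probes (adjusted p = 0.0128) or with intensities of 0.1 or more (0.0103), and ranged up to 0.258 at the preset correlation.

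Acute phase proteins, which the liver secretes into plasma during inflammation, were higher for 11 and lower for 1 of 21 members (13 and 1 adjusted over the list alone), with a median log2 change of 1.01. Besides A2m, Lcn2 (a siderophore-binding protein) rose by 3.56 ± 0.91, Orm1 (alpha-1-acid glycoprotein) by 3.01 ± 0.53, Lbp (LPS-binding protein) by 2.12 ± 0.63 and C-reactive protein (Crp) by 0.53 ± 0.12. The metallothionein gene Mt1 fell by 1.91, and hepcidin (Hamp) stood at 2.85 ± 0.90 with an adjusted p of 0.0546. Camera gave an adjusted p of 0.000349, and adjusted p = 0.254 with an estimated correlation. In Control replicate 3 the mean of this list stood at log2 0.44 against the pool, with the other Control arrays at -0.58 to -0.31 and the LPS arrays at 0.74 to 1.17. Without that array 12 members were higher and 1 lower. Without LPS replicates 1 or 4, 7 were higher, and without Control replicates 2 or 4 or LPS replicates 2 or 3, 6. Lbp lost its call without any 1 of the 7 other arrays (1.73 to 2.15, and 2.78 without Control replicate 3), Lcn2 without any 1 of 6, every one but Control replicate 3 and LPS replicate 4 (3.17 to 3.47, and 4.51 without LPS replicate 4, whose value of 0.58 lay apart from 4.22 to 4.62 on the other LPS arrays), and Crp without LPS replicates 2 or 3 (0.51 and 0.52). Hamp passed without Control replicate 1 (3.83), without dim probes, with loess (2.82), with a variance trend and with the reference genes' mean at 0 (2.74).

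**Figure D2:**
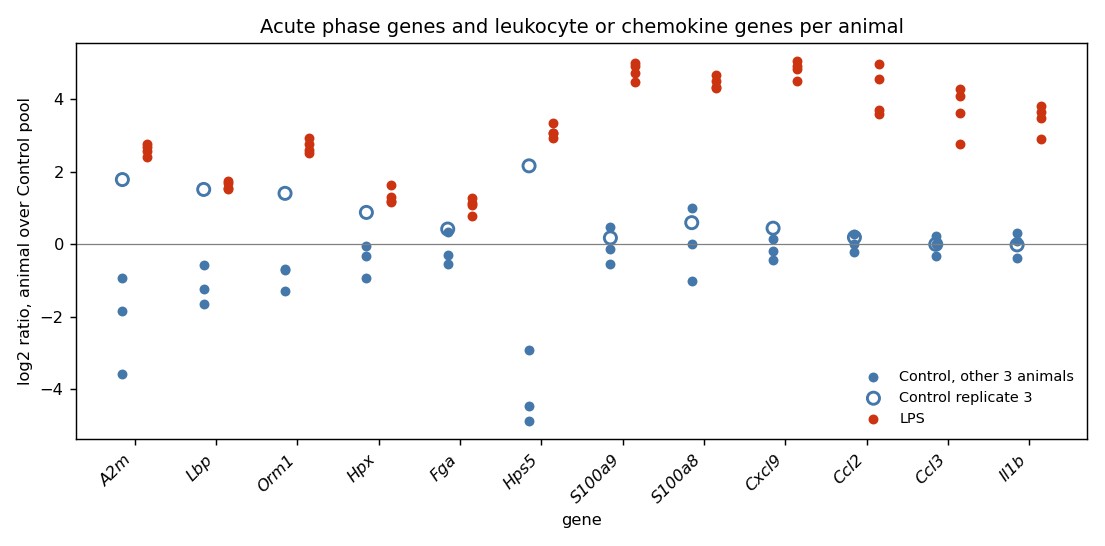
Log2 ratio of animal over Control pool (vertical axis) per animal for 5 acute phase genes, Hps5 and 6 leukocyte, chemokine or cytokine genes, with Control replicate 3 as an open circle. In A2m, Lbp, Orm1, Hpx and Hps5 the open circle lies between the other Control animals and the LPS animals. For Lbp it is close to the LPS animals, at log2 2.67 above the mean of the other Control animals, with the LPS mean at 2.78. In S100a9, Ccl2, Ccl3 and Il1b it lies among the other Control animals. For Cxcl9, S100a8 and Fga it is above their mean by 0.60, 0.59 and 0.58, with the LPS means at 4.99, 4.46 and 1.23.

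Plasma proteins that inflammation lowers were lower for 7 and higher for 1 of 12 members (8 and 1 adjusted over the list alone), with a median of -0.44. Serpina6 and Alb fell as given above, paraoxonase (Pon1) fell by 1.23 and the vitamin E carrier afamin (Afm) by 1.07, while Gc, the vitamin D carrier, was higher at 0.50. Camera gave an adjusted p of 0.00162, and adjusted p = 0.181 with an estimated correlation. Complement genes went both ways, with 4 higher and 4 lower of 17 (5 and 4 adjusted over the list alone) and a camera adjusted p of 0.434. C6 rose by 1.15 ± 0.31 and Serping1, the C1 inhibitor, stood at 1.09 with 1 Control and 3 LPS values, while C8g fell by 1.15 and properdin (Cfp) by 0.92. The others past the test were C2 and Masp2, higher, and Cfd and C7, lower. Without Control replicate 3, which stood at 0.25 in the list mean with the other Control arrays at -0.26 to -0.02 and the LPS arrays at 0.01 to 0.10, 9 complement genes were higher. Without Control replicate 1, 1 was higher, and without Control replicate 4 or LPS replicates 1, 3 or 4, 2. C6 lost its call without Control replicates 1 or 4 or LPS replicates 1, 3 or 4, at 0.91 to 1.26, and its brightest probe alone did not pass (0.67). Coagulation genes were higher for 5 and lower for 5 of 18 (5 and 5 adjusted over the list alone, camera adjusted p = 0.519). Fibrinogen alpha (Fga) rose by 1.09, Tfpi by 1.00 and tissue plasminogen activator (Plat) by 0.94, and protein C (Proc) fell by 0.60. Plaur was also higher, and F5, F12, Plau and F13a1 lower. Without Control replicates 2 or 3 or LPS replicates 1 or 4, 3 coagulation genes were higher.

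Cytokines, chemokines and adhesion molecules were higher for 13 and lower for 2 of 29 members (16 and 2 adjusted over the list alone), with a median of 0.69 and a camera adjusted p of 1.6e-06, and adjusted p = 0.161 with an estimated correlation. Cxcl9, Ccl2, Ccl3 and Il1b rose as given above, and the chemokines Ccl4 (-0.58) and Cx3cl1 (-0.38) were lower, while the number of lower members was 1 without Control replicate 1 or LPS replicate 2. Tnf (0.10 ± 0.07), Il6 (0.09 ± 0.12) and the inducible nitric oxide synthase gene Nos2 (0.00 ± 0.08) did not pass the test at 24 hours. The probes of Tnf and Il6 were dim, at mean intensities of 0.054 and 0.053 printed in steps of 0.01, with 4 and 3 of their 4 Control ratios at exactly 0, so a small change there was not detectable. In the Toll-like receptor and NF-kB pathway, 12 were higher and 1 lower of 24 (13 and 3 adjusted over the list alone), with a median of 0.31. Tlr2, a receptor of bacterial lipoproteins, rose by 1.63 ± 0.12, Stat3 by 1.42 ± 0.13, Irak3, a negative regulator of the pathway, by 1.20 ± 0.12 and the kinase gene Map3k8 by 1.12 ± 0.14. Cd14 stood at 0.03 ± 0.26 and Tlr4 at -0.14 ± 0.09, and neither passed, while the NF-kB subunit Rela was lower at -0.27. Camera gave an adjusted p of 0.00483, and adjusted p = 0.181 with an estimated correlation. The list call ended without the 50% dimmest probes (adjusted p = 0.0768, with a range of 0.00126 to 0.0768 over the alternatives at the preset correlation), and 7 members were higher without LPS replicates 2, 3 or 4. The mean of the neutrophil and monocyte markers stood at log2 0.98 ± 0.15 (SD, n = 4) in the same LPS arrays.

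Interferon-stimulated genes were higher for 12 and lower for 1 of 33 members (15 and 1 adjusted over the list alone), with a median of 0.48. The GTPase genes Ifi47 and Irgm both rose by 2.15, and the immunoproteasome genes Psmb10 and Psmb9 both by 1.67, while Stat2, a factor of interferon signalling, was lower at -0.57. For these genes the camera adjusted p was 2.06e-05, and adjusted p = 0.254 with an estimated correlation. Control replicate 3 stood at 0.29 in the mean of this list and the other Control arrays at -0.14 to -0.08. Genes of MHC class I presentation were higher for 7 and lower for 1 of 14 (10 and 1 adjusted over the list alone), with a median of 0.53. They include the proteasome activator gene Psme2 (0.96 ± 0.17), RT1-M3-1 (0.90 ± 0.12) and RT1-A2 (0.68 ± 0.15), whose 5 probes ranged from 0.21 to 1.09 and whose brightest probe alone did not pass (0.21), while RT1-T24-1 was lower at -0.39. In the LPS arrays this list's mean was highest in replicate 1 (0.75) and lowest in replicate 2 (0.25), as was that of the lymphocyte markers (0.70 and 0.17) and of MHC class II (0.81 and 0.00). Camera gave an adjusted p of 0.000427, and adjusted p = 0.251 with an estimated correlation. Of 11 MHC class II genes 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.198), the regulator Ciita at 0.64 and RT1-DMb at 0.44. Without Control replicate 3, LPS replicate 3 or LPS replicate 4, 0 of them were higher, and without Control replicates 1, 2 or 4 or LPS replicate 1, 1. RT1-DMb lost its call without any 1 of 6 arrays, every one but Control replicate 2 and LPS replicate 2 (0.36 to 0.46) and with the reference genes' mean at 0 (0.33), and Ciita without Control replicates 2 or 3 or LPS replicates 3 or 4 (0.60 to 0.66).

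Iron genes were higher for 8 and lower for 1 of 15 (9 and 1 adjusted over the list alone), with a median of 0.46. Hemopexin (Hpx), which binds free heme, rose by 1.43 ± 0.35, the transferrin receptor (Tfrc) by 1.32 ± 0.21 and Id1 by 0.99 ± 0.14, while the iron exporter Slc40a1 (ferroportin) was lower at -0.71. Camera gave an adjusted p of 0.00503, and adjusted p = 0.161 with an estimated correlation. Hpx lost its call without Control replicates 2 or 4 or LPS replicates 2, 3 or 4, at 1.33 to 1.48. Without Control replicates 2 or 4, 5 iron genes were higher, and without LPS replicates 2 or 3, 4.

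Cytochrome P450 and other phase I genes were lower for 23 and higher for 2 of 35 members (27 and 3 adjusted over the list alone), with a median log2 change of -0.94. The carboxylesterase gene Ces1d fell by 2.78, Cyp3a23-3a1 by 2.64, aldehyde oxidase (Aox1) by 2.38 and Cyp2c11, the main P450 of the male rat liver, by 2.03, while Cyp2c12 (1.73 ± 0.39) and Cyp1b1 were higher. The camera adjusted p was 4.56e-07, and adjusted p = 0.181 with an estimated correlation. Cyp3a2 and Cyp2e1 had no value on the Control arrays. On the 4 LPS arrays they stood at -2.43 ± 0.95 and -1.70 ± 0.46 (SD, n = 4) against the Control pool, and Igf1 stood at -0.42 on the 1 LPS array that gave it a value. The Cyp3a2 probe was bright, at a mean intensity of 39.5. Why Control ratios are missing is not stated, so the size of the Cyp3a2 and Cyp2e1 values is uncertain. Phase II conjugation genes were lower for 14 and higher for 1 of 33 (15 and 1 adjusted over the list alone), with a median of -0.44. Among the glucuronosyltransferases Ugt2b1 fell by 2.83 and Ugt2b37 by 1.68, the sulfotransferase Sult1c2 fell by 2.54 and the glutathione transferase Gsta2 by 1.71, while the acetyltransferase Nat1 was higher at 0.71, except without LPS replicate 3. The camera adjusted p was 0.000189, and adjusted p = 0.240 with an estimated correlation. Control replicate 3 stood at -0.26 in the mean of this list, with the other Control arrays at 0.00 to 0.04 and the LPS arrays at -1.04 to -0.54. Gsta2 lost its call without Control replicates 1 or 4 or LPS replicate 1, at -1.65 to -1.53. The hepatocyte markers had a median change of -0.58 in the same arrays. Their list mean, over 11 members with values on all arrays, went from -0.02 in Control to -0.32 in LPS. That of the phase II genes went from -0.05 to -0.68. The raised Serpina1 is among the 11 and lifts the hepatocyte mean. These means therefore do not show that phase II genes fell further than hepatocyte markers. P450, Ugt2b and Sult genes have close paralogs, and a probe may not part them.

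Bile acid synthesis genes were lower for 3 and higher for 2 of 11 (4 and 2 adjusted over the list alone, camera adjusted p = 0.0900). Cyp27a1, which starts the acidic pathway, fell by 1.40, Slc27a2 by 1.06 and Hsd17b4 by 0.73, and Acox2 rose by 1.04 with 2 Control and 3 LPS values and Cyp7b1 by 0.56. The list passed with loess (adjusted p = 0.0451, with a range of 0.0451 to 0.234 over the alternatives at the preset correlation). Cyp7a1, the rate-limiting enzyme of the classical pathway, stood at 0.01 ± 0.33 and did not pass. Hepatobiliary transporters were lower for 8 and higher for 4 of 22 (10 and 4 adjusted over the list alone), with a median of -0.36. The bile acid importer Slc10a1 (NTCP) fell by 1.74, Slco1a4 by 1.05, and the canalicular exporters Abcc2 (MRP2) by 0.96 and Abcb11 (BSEP) by 0.71. The multidrug exporter Abcb1b rose by 1.53 ± 0.30 and Abcg2 by 1.14 ± 0.34; Abcg2 lost its call without any 1 of 7 arrays, every one but LPS replicate 1, at 0.92 to 1.25. Atp8b1 and Slc47a1 were also higher, and without Control replicates 1 or 3 or LPS replicates 1 or 2, 2 members were higher, and without LPS replicates 3 or 4, 1. The camera adjusted p was 0.0357, and adjusted p = 0.284 with an estimated correlation. That list call ended without Control replicate 1 (adjusted p = 0.0638), Control replicate 4 (0.0575), LPS replicate 1 (0.0506) or LPS replicate 4 (0.0513), and with scale normalization (0.0548), each probe alone (0.0549) or the reference genes' mean at 0 (0.0565), with a range of 0.0130 to 0.0638 over the alternatives at the preset correlation.

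Liver transcription factors and nuclear receptors were lower for 8 and higher for 2 of 28 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0741). Besides Nr0b2, Pparg fell by 1.21, the xenobiotic receptors PXR (Nr1i2) by 0.87 and CAR (Nr1i3) by 0.83, while Cebpd (0.82) and Nr5a2 (0.58) were higher. Rxra stood at -0.14 ± 0.05 and did not pass, except with the reference genes' mean at 0 (-0.24). Nr1i3 lost its call without any 1 of 6 arrays, every one but Control replicate 2 and LPS replicate 2, at -0.87 to -0.70, and this list passed without Control replicate 1 (adjusted p = 0.0488) and with each probe alone (0.0317), with a range of 0.0317 to 0.206 over the alternatives at the preset correlation.

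Genes of cholesterol synthesis and uptake were higher for 20 and lower for 0 of 25 members (21 and 1 adjusted over the list alone), with a median log2 change of 0.88. Idi1 rose by 2.16 ± 0.26, squalene epoxidase (Sqle) by 2.15 ± 0.28, Dhcr7 by 1.99 ± 0.20 and Mvd by 1.85 ± 0.12, all enzymes of the pathway. The list mean was 0.94 ± 0.04 in LPS and -0.01 ± 0.17 in Control (SD, n = 4), the camera adjusted p was 1.2e-10, and adjusted p = 0.161 with an estimated correlation. Control replicate 3 stood at 0.23 in the list mean and the other Control arrays at -0.15 to 0.00, and 1 member was lower without Control replicate 3 or LPS replicate 2. Fatty acid oxidation and ketogenesis genes were lower for 16 and higher for 0 of 25 (17 and 0 adjusted over the list alone), with a median of -0.59. The peroxisomal enzyme gene Ehhadh fell by 2.78, Bdh1, an enzyme of ketone bodies, fell by 1.52 on the log2 scale, and Cpt1a, the gate of mitochondrial fatty acid import, by 1.63 with 2 Control values. The camera adjusted p was 4.4e-06, and adjusted p = 0.181 with an estimated correlation. The median of the hepatocyte markers was -0.58 in the same arrays. Their list mean, which the raised Serpina1 lifts, was -0.32 in LPS and -0.02 in Control. The fatty acid oxidation list mean was -0.73 in LPS and -0.03 in Control, which does not show a further fall than that of hepatocyte markers. Fatty acid and triglyceride synthesis genes were higher for 6 and lower for 3 of 21 (7 and 6 adjusted over the list alone, camera adjusted p = 0.206). The elongase Elovl6 rose by 2.05, fatty acid synthase (Fasn) by 1.33 and Mlxipl (ChREBP) by 1.05, and the desaturase Fads2 fell by 1.11. Me1 and Lpin2 were the others lower, and 1 gene was lower without Control replicate 2 or LPS replicates 2 or 4.

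Urea cycle and amino acid catabolism genes were lower for 11 and higher for 1 of 29 (13 and 1 adjusted over the list alone), with a median of -0.55. Besides Sds, the methyltransferase Gnmt fell by 1.40, Kmo, of the kynurenine pathway, by 1.21 and glutaminase 2 (Gls2) by 0.99, while Bhmt, a homocysteine methyltransferase, stood at 0.87 with 1 Control value, and was not called, or could not be tested, when any 1 array was left out. The camera adjusted p was 8.99e-05, and adjusted p = 0.242 with an estimated correlation. Control replicate 3 stood at -0.35 in the list mean, with the other Control arrays at -0.11 to 0.18 and the LPS arrays at -0.75 to -0.59. For comparison, the hepatocyte markers, which share Cps1, Tat and Hpd with this list, had a median of -0.58. Their list mean was -0.32 in LPS and -0.02 in Control, against -0.66 and -0.04 for the amino acid list. The raised Serpina1 lifts the hepatocyte mean, so these means do not show a further fall of the amino acid list. Gluconeogenesis and glycogen genes were lower for 7 and higher for 0 of 20 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0519). Glucose-6-phosphatase (G6pc1) stood at -1.49 with 1 Control value, and liver glycogen synthase (Gys2) fell by 1.30 and the glucose-6-phosphate transporter Slc37a4 by 0.92. The list passed without Control replicate 3 (adjusted p = 0.0244) or LPS replicate 2 (0.0477), with loess (0.0178) and with intensities of 0.1 or more (0.0499), with a range of 0.0178 to 0.258 over the alternatives at the preset correlation, and 4 members were lower without LPS replicate 3. Gys2 lost its call without Control replicates 1 or 2 or LPS replicates 1, 3 or 4 (-1.29 to -1.19), and G6pc1 without LPS replicates 2 or 3 (-1.44 and -1.54), with a variance trend (adjusted p = 0.0756) or without moderation (0.0902), with a range of 0.00831 to 0.110 over its alternatives.

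Endoplasmic reticulum stress genes were higher for 11 and lower for 3 of 21 (12 and 4 adjusted over the list alone), with a median of 0.45. Creld2 rose by 2.47 ± 0.33, the chaperone gene Dnajb11 by 1.64 ± 0.23 and the transcription factor gene Ddit3 (CHOP) by 1.57 ± 0.14, while Trib3 was 2.83-fold lower and Herpud1 (-0.79) and Atf4 (-0.25) were lower. The camera adjusted p was 0.00289, and adjusted p = 0.284 with an estimated correlation, and Control replicate 3 stood at 0.29 in the list mean, with the other Control arrays at -0.16 to -0.09. Oxidative stress genes were higher for 4 and lower for 6 of 20 (4 and 7 adjusted over the list alone, camera adjusted p = 0.265). Besides Mt1, the glutathione synthesis gene Gclm fell by 1.43 and catalase (Cat) by 1.11, while Nqo1 rose by 1.36, and Txn1 and Hmox1 were higher. Nqo1 lost its call without LPS replicates 1, 2 or 3, at 1.29 to 1.35. Cell division genes were higher for 13 and lower for 0 of 32 (13 and 0 adjusted over the list alone), with a median of 0.33. The replication helicase gene Mcm5 rose by 2.22 ± 0.33, cyclin A2 (Ccna2) and topoisomerase Top2a both by 1.18, and Mki67 rose 2.15-fold. For this list the camera adjusted p was 3.06e-06, and adjusted p = 0.181 with an estimated correlation. Ccna2 lost its call without LPS replicates 1, 3 or 4, at 1.05 to 1.16, and 8 members were higher without LPS replicate 4. The mean of this list was lowest in LPS replicate 2 (0.23, the other LPS arrays at 0.47 to 0.52), as was that of the lymphocyte markers (0.17, the others at 0.37 to 0.70) and of the neutrophil and monocyte markers (0.81, the others at 0.90 to 1.13).

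Clock genes moved in opposite directions, 2 higher and 5 lower of 14 (3 and 5 adjusted over the list alone, camera adjusted p = 0.271). Bmal1 (Arntl), an activator of the clock, rose by 2.18 ± 0.39, and Dbp, Per1 and Per3, which that activator drives, were lower at -2.52, -1.76 and -1.24, as were Per2 and Tef, while Nfil3 was higher at 0.90. Per1 lost its call without LPS replicate 3, at -1.60, where 3 clock genes were lower. Oxidative phosphorylation genes were higher for 3 and lower for 2 of 29 (2 and 1 adjusted over the list alone, camera adjusted p = 0.136), with Cycs at 0.61, Ndufs1 at 0.57, Atp5po at 0.40, Cox4i1 at -0.33 and Atp5f1c at -0.21. Ndufs1 lost its call without any 1 of 6 arrays, every one but Control replicate 4 and LPS replicate 1 (0.45 to 0.58), and Cox4i1 without LPS replicates 1 or 4 (-0.31 and -0.29), where 0 members were lower; without Control replicates 1, 2 or 4 or LPS replicate 3, 1 was. The genes often used as references for normalisation were higher for 4 and lower for 2 of 12 (6 and 3 adjusted over the list alone, camera adjusted p = 0.271). Actb rose by 0.77, Ppia by 0.44 and Rpl13a by 0.38, and Polr2a fell by 0.32; Gapdh was also higher and Rps18 lower. Without Control replicates 1, 3 or 4 or LPS replicates 2 or 3, 2 reference genes were higher, and without Control replicates 1 or 4 or any 1 LPS array, 1 was lower. Rpl13a lost its call without any 1 of 6 arrays, every one but Control replicate 2 and LPS replicate 4, at 0.33 to 0.40, and with the reference genes' mean at 0 (0.27).

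**Figure D3:**
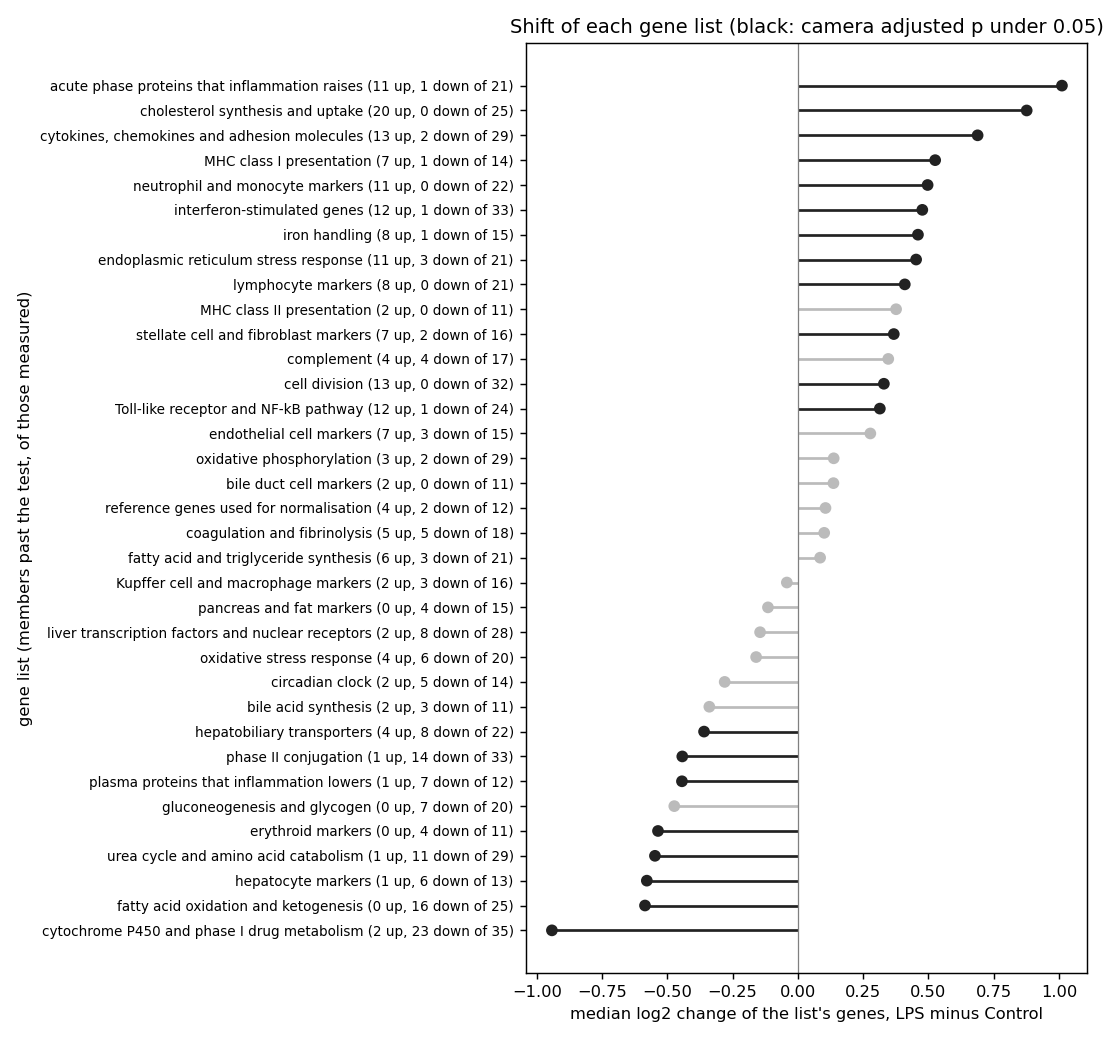
Median log2 change, LPS minus Control (horizontal axis), of the members of each of the 35 gene lists, black where the camera adjusted p is under 0.05, with the numbers of members past the limma test. Of the lists, 12 were called higher and 8 lower, from acute phase proteins at 1.01 down to cytochrome P450 and phase I genes at -0.94.

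Over all 35 lists, camera with a preset correlation called 12 higher and 8 lower, and with an estimated correlation 0. The exact permutation test on each list's mean (two-sided, 70 assignments) gave its smallest possible p of 0.0286 for every called list, and also for 11 of the 15 lists not called, so it does not set the called lists apart. Of the 144 named genes past the test, 3 (Ahsg, Serping1 and G6pc1) had 1 Control value, and of the other 141, 118 passed whichever 1 array was left out, while quantile normalization ended 74 of the calls and scale normalization 88. Such genes with 1 Control value are called on the assumption that this array varies as the LPS arrays do; 6 called list members are of this kind, the other 3 being Serpina3n, Fbp1 and Bhmt. The called genes Abcb1b, Tlr2, Ciita, Ccna2, Top2a, Serpina1, Mmp9, Lyz2 and Cftr had mean intensities under 0.1, so the size of their changes is coarse. Genes given above as exceptions in a list's direction, or as the remaining members of a small count, were chosen after their values were seen: Reln, Col3a1, Vsig4, Stab2, Gc, C2, Masp2, C7, Plaur, F5, F12, Plau, F13a1, Ccl4, Cx3cl1, Rela, Stat2, RT1-T24-1, Slc40a1, Cyp2c12, Cyp1b1, Nat1, Cyp7b1, Atp8b1, Slc47a1, Cebpd, Nr5a2, Me1, Lpin2, Bhmt, Herpud1, Atf4, Txn1, Hmox1, Per2, Tef, Nfil3, Atp5f1c, Gapdh, Rps18, Serpina3n and Fbp1.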

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

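Tests of the Control replicate 3 and cell marker patterns here were chosen after the result was seen; the counts over other splits of the arrays were planned. Groups of 4 values were looked at for named genes (299) and list means (70). Chance gives 1 array far from the other 3 in about 1 in 20 groups, or 18.5, for independent values that are not rounded. Rounding puts several arrays at the same value here, and flagged genes recur in flagged lists, so this number is only a rough guide. In all, 34 groups held 1 array far from the other 3. Control replicate 3 was that array in 11 of them.

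Control replicate 3 stood high in Lcn2 (log2 0.94 against the pool), Irgm (0.62), Creld2 (0.74), Dnajb11 (0.62) and Ddit3 (0.37). It also stood high in the means of the interferon-stimulated list (0.29) and the endoplasmic reticulum stress list (0.29). It stood low in Aox1 (-0.49), Cela1 (-0.23) and the phase II list mean (-0.26). Il6 stood apart in this array too (0.42), but on a dim probe. The other Control arrays were at exactly 0 for Il6, the value that rounded intensities give. The Il6 value therefore does not show that Il6 was raised in that animal. The acute phase genes of this array lay on the LPS side of the other Control arrays, by a median of log2 1.00 over the 10 acute phase genes that rose with LPS, from 0 to 3.91 for A2m. An admixture of LPS liver RNA that gives those values would be 35.1% of the sample and would put the 55 other genes raised at least 4-fold at a median of 1.42. Their observed median was 0.20, with quartiles of -0.03 and 0.60, which argues against such an admixture. An exchange of labels with an LPS array needs an LPS array out of place, and the lowest mean correlation of an LPS array with the other LPS arrays was 0.71, which argues against it. No biological explanation was tested, as the labels give no factor within the Control group; an acute phase response in that animal before sampling remains open as a hypothesis.

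Among the other Control arrays, replicate 1 stood apart in Hamp (1.63), replicate 2 in Zfp354a (-1.12), RT1-DMb (0.21), Ccna2 (-0.9999), Mmp9 (-0.58) and Plin1 (0.17), and replicate 4 in Nos2 (-0.11) and Top2a (0.42). In Ccna2, Mmp9, Plin1 and Top2a the other Control arrays were at exactly 0, the value that rounded intensities give. LPS replicate 1, the array under the other dose header, stood apart in Zfp354a (-3.62), Stat3 (1.18), Ces1d (-2.15), Ehhadh (-2.18), Clec4f (-1.74) and the means of the Toll-like receptor (0.24) and Kupffer cell (0.094) lists. In Zfp354a, Stat3, Ces1d, Ehhadh and Clec4f it lay nearer to the Control arrays than the other LPS arrays did. LPS replicate 2 stood apart in Slc27a2 (-0.83) and the cell division (0.23) and bile duct (0.11) list means, LPS replicate 3 in Ugt2b37 (-1.89), Cpt1a (-1.33) and the phase II list mean (-1.04), and LPS replicate 4 in Lcn2 (0.58, the others at 4.22 to 4.62) and Mt1 (-2.75).

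The rise of neutrophil, monocyte and lymphocyte markers was set against 2 technical explanations. A lower share of hepatocyte RNA raises the markers of every other cell type alike. The erythroid list changed by -1.78 ± 0.18 (SE) relative to the neutrophil and monocyte list on the log2 scale. That value also depends on reticulocyte numbers, so it does not decide the point. Mean log2 changes were 1.00 for neutrophil and monocyte markers, 0.42 for lymphocyte and 0.53 for stellate cell and fibroblast markers. They were 0.22 for bile duct, 0.12 for endothelial and -0.07 for Kupffer cell and macrophage markers. Their medians lay closer together, at 0.50, 0.41, 0.37, 0.14, 0.28 and -0.04 in the same order. These lists did not rise alike, though LPS may change a marker within its cell. More blood left in the LPS livers raises erythroid transcripts, and their list changed by -0.78 ± 0.16; reticulocyte numbers in the blood were not measured. The uneven changes of the cell marker lists argue against a lower hepatocyte share as the whole cause only if LPS left these markers unchanged within their cells. The erythroid fall argues against more blood only if reticulocyte numbers did not fall. More leukocytes in the LPS livers, or higher transcription of these genes in cells already there, remain open, and the arrays do not part them.

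The counts of called genes were larger in the real split than in any other of the 35 splits of the 8 arrays into 4 and 4. The real split gave 1976 higher, 1689 lower and 553 at least 2-fold changed genes, and the highest other split gave 1 in each case. Thus 1 of 35 splits reached each count, a share under 0.05 and the smallest that 35 splits allow. Every other split mixes LPS and Control arrays within a group, which widens the spread and lowers its counts. The counts also come from the same fit, so they are not separate tests. For the number of called lists, 2 of 35 splits gave as many, the real one with 20 and another with 21. Chance cannot be excluded there at a share under 0.05. The other split exchanged Control replicate 3 and LPS replicate 2, and so kept 3 of 4 arrays of each group together.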

How the results depend on the processing

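Settings chosen after seeing the data were the rounding noise, the linear Control mean, the intensity limit of 0.1 and leaving out the array under the middle dose header. No direction of a called list or called named gene was reversed in the settings that tested it. Of all called genes, the sign turned for 19 with the brightest probe (4 past the test), 7 without the 50% dimmest probes (2 past it), 2 without the 25% dimmest and 4 with intensities of 0.1 or more, and for 0 in the other settings compared gene by gene; these settings change which probes of a gene are averaged. Quantile normalization gave 643 higher, 417 lower and 204 at least 2-fold changed genes, and scale normalization 452, 318 and 121. Both give the Control and the LPS arrays 1 common spread, although the SD of the ratios was 0.22 to 0.34 on Control and 0.50 to 0.57 on LPS arrays, and so widen the noise of the Control arrays by construction; the 1060 and 770 genes called were among the main calls in the same direction. Subtracting the mean of the reference genes gave 2886 lower genes, and testing the LPS arrays against the pool alone gave 3095 lower genes; the former lowers every gene alike, and the latter leaves out the Control animals' own spread. An adjusted p under 0.01 left 1067 higher and 834 lower genes, and an unadjusted p under 0.01 with at least 2-fold change 351 and 197, by the construction of stricter limits. With an estimated correlation, camera called 0 of the 35 lists, with the smallest adjusted p at 0.133, while 20 were called with the preset correlation and 30 with fry, which does not compare a list with other genes.

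The replicate numbers, shared between the groups, did not pair the arrays. Same-numbered arrays deviated from their group means with correlations across genes of -0.01, -0.01, 0.03 and 0.17. Only number 4 correlated best with its own. With the replicate block 1510 genes were higher and 1118 lower, from 1976 and 1689, and 2498 calls (68.2%) were kept in the same direction; the transporter list was no longer called and the bile duct list was. The block adds terms that leave fewer residual degrees of freedom, which by itself lowers the number of called genes. What moved the calls of the transporter and bile duct lists was not tested.

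Leaving out 1 array gave 1511 to 1842 higher genes, 1244 to 1616 lower genes, 490 to 596 at least 2-fold changed genes, 18 to 22 called lists, 0 Control probes off the pool, and 6279 to 8139 LPS probes off the pool. All other settings left these counts within 1.5 times. Over all settings, called lists kept their call in 484 comparisons and lost it in 36, and lists not called gained one in 28 and did not in 361. Called named genes kept their call in 3086 and lost it in 331, and those not called gained one in 8 and did not in 178; quantile and scale normalization ended 74 and 88 named gene calls. Counts of list members stayed within 1.5 times in 1467 comparisons and moved further in 283. In 20 draws of noise within the printed rounding step, 1796 to 1847 genes were higher and 1401 to 1461 lower. Normexp background correction was not run, since the deposited intensities are relative and have no background column, and list tests without moderation were not run. Signal limits dim genes, as 35.6% of values have both intensities under 0.1.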

Other observations

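The tests of the Hps5 probe, the pool and the female-biased list alone were chosen after the result was seen, the Hps5 and pool ideas coming from A2m, which both tests leave out; the test of the female-biased against the male-biased list was fixed before its value was seen. Genes with sex-biased expression in the adult rat liver, listed from background knowledge after the data were examined, shifted with LPS, although the sex of the rats is not in the labels. Of the male-biased transcripts besides Cyp2c11, Obp3 (an alpha-2u globulin) stood at log2 -2.07 ± 0.37, Cyp2c13 at -1.35 ± 0.15, Cyp2a2 at -0.73 ± 0.20 and Slco1a1 at -0.72 ± 0.21, all past the test, as was carbonic anhydrase 3 (Car3), and Cyp4a2 at 0.05 ± 0.45 was not. Cyp2c12, the female P450 steroid hydroxylase, rose by 1.73 ± 0.39 (adjusted p = 0.0160), with 3 probes from 0.19 to 2.87, in contrast to Cyp2c11.

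A hypothesis is that LPS shifted the liver from male-biased to female-biased transcripts. Without Cyp2c11 and Cyp2c12, the mean of 7 female-biased genes changed by 0.71 ± 0.12 (SE) on the log2 scale relative to the mean of 6 male-biased genes (exact two-sided permutation p = 0.0286, the smallest the design allows). Of the male-biased genes, Cyp2c13, Cyp2a2 and Cyp4a2 are also in the phase I list and Slco1a1 in the transporter list. Of the female-biased genes, Cyp2c7 and Cyp3a9 are in the phase I list and Sult2a1, Sult2a2 and Sult2a6 in the phase II list. Those lists fell too, so the difference does not part a sex-biased shift from their fall. The female-biased mean itself changed by -0.43 ± 0.14, with Prlr at -1.40 and Cyp2c7 at -1.07 past the test, so the difference comes from a larger fall of the male-biased genes and not from a rise of the female-biased ones. The rise of Cyp2c12 stands alone in this list and its probes, like those of other P450 genes, can bind paralogs.

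The probe named Hps5 may read an acute phase transcript. Hps5 encodes a part of a lysosome-related sorting complex, but this probe had a mean intensity of 20.3, spread over the Control animals as A2m did and rose most of all named genes on the log2 scale. Of the 100 genes that moved most like it within the groups, 2 were acute phase genes (Lbp and Orm1) of 16 among 13942 compared, A2m left out (Fisher's exact test, one-sided p = 0.00572). Lbp and Orm1 also stand high in Control replicate 3, so this likeness does not part a probe that reads another transcript from Hps5 itself moving with that animal. Fisher's test takes the genes as independent, which genes that move together on 1 array are not, so its p-value does not measure support. In the GRCr8 gene table Saa3 and Saa4, genes of the serum amyloid A family of acute phase proteins, lie within 5 genes of Hps5, and Saa4 itself rose by 1.27 ± 0.23 here. Probe sequences were not used here, so regulation of Hps5 itself remains open.

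The Control pool may hold the RNA of these same 4 Control livers in equal parts. Over 49 genes that vary between the Control animals (SD over 1, intensity of 0.1 or more), the mean of the 4 linear ratios to the pool lay at a median distance of log2 0.031 from the pool, against 0.54 at least and 0.94 in the median over 1000 random pools. Each random pool took 1 Control animal per gene as the reference, which spreads more than a pool of unrelated animals would. If so, a gene that is high in 1 Control animal has a mean Control log2 ratio below 0, which was -0.42 in the median over these genes. The log2 difference between the groups then exceeds that of the linear means. For Hps5 it was 5.64 from the mean of the logs and 2.88 from the log of the mean Control ratio, 1.17. For A2m it was 3.75 from the mean of the logs and 2.49 from the log of the mean Control ratio, 1.09.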
